A study of Synechocystis sp. PCC 6803 with 16 samples.

How the data were processed

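RNA from the wild type (WT) and a ΔcyabrB2 strain of Synechocystis sp. PCC 6803 was hybridised to 16 one-colour Agilent arrays, 6 WT arrays and 2 mutant arrays at each of 2 CO2 levels. Per the labels, RNA was labelled with Cy3 directly, with no cDNA step, so that each probe reads the strand it was designed for. The deposited scanner tables hold spot intensity values made with Agilent Feature Extraction 10.7.3.1, per the file headers. Their processed signal is an intensity from which Feature Extraction had subtracted the background, per the file headers; it had been spatially detrended within the array, spots at background held a surrogate value, and nothing had been scaled between arrays. The mean spot signal and the median local background in the same deposited tables are unscaled intensity values, and 0/1 flags mark spots well above background, saturated spots and outlier spots. The deposited series table holds log2 values by the authors. Its columns had medians from 11.4439 to 11.4448 and correlated with the log2 mean spot signal of the same array at r = 0.995 to 0.9996, across spots, and with the log2 processed signal at 0.902 to 0.948. Their scale is therefore log2 of the mean spot signal with equal medians, higher values stand for more signal, and the method that made the medians equal stays unknown. The submitters' processing notes name limma and give no normalization.

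The values tested were log2 processed signals minus the 75th percentile of each array over its probes. Control spots were left out, and outlier spots too, except in 73 cases in which all spots of a probe on an array were marked as outliers. Spots of a probe were averaged, then probes of a feature. The arrays carried 20363 probes for 8830 features, named on the array by locus tag or by a class of transcript, and all 16 value columns could be matched to an array, with 0 unmatched. A feature was tested if at least 1 of its probes was well above background on at least 2 arrays, which held for 8427 features, 3345 of them protein-coding genes. On each array 77.7 to 94.1% of spots were well above background, and the number of arrays limits the precision.

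Groups and replicate numbers were taken from the labels. limma 3.58.1 in R 4.3.3 fitted 1 coefficient per group to all 16 arrays, with empirical Bayes moderation, and 5 contrasts were taken: low against high CO2 in WT and in the mutant, mutant against WT at high and at low CO2, and the difference between the strains' responses to low CO2. P values were adjusted with Benjamini and Hochberg's method over the 8427 features, and a feature counts as changed at an adjusted p under 0.05. Errors after ± are standard errors of limma's fit. Gene lists with at least 3 measured members were tested among the protein-coding genes with camera at a preset correlation of 0.01 and again with an estimated correlation; 24 lists had that many, and their p values were adjusted within each comparison. A gene not well above background on any array of a group has only a bound there: the mean of the other group was set against the higher of the gene's own signal and the lowest signal of a probe well above background, array by array, and the result is written as at least N-fold.

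The design, the gene lists, the rule for the named genes and the alternatives were written before the data were examined, except 3 alternatives that were chosen after: averaging the arrays of a scan period, the replicate block with the mutant low CO2 numbers crossed, and the fits within a scan period. The rule takes, in each comparison, the 8 genes with the largest rise and the 8 with the largest fall among changed genes whose arrays did not overlap between groups; all members of the lists of inducible carbon uptake genes, of the flv4-2 operon and of carbon regulators; sll0822; up to 4 members of each list that camera called; and the 3 features other than genes with the largest change in each direction. For the response difference the overlap was not used. Gene symbols come from these lists, because the array names genes by locus tag only and 0 of its tags were found in the reference gene table supplied. No coordinates are given for the same reason, and few locus tags without a symbol are printed.

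The fit was tested on simulated data for 8427 features, 200 of them changed. With independent arrays, 2-fold changes were recovered in 79.1% of cases for WT low against high CO2, 43.3% for mutant against WT at high CO2 and 40.3% for mutant against WT at low CO2; 4-fold changes in 97.0%, 89.4% and 86.4%. Unchanged features made up 4.11%, 4.00% and 3.33% of the calls. Arrays of a group scanned in the same period were then made to resemble each other as much as the real ones do (a correlation of 0.863). The same fit then also called 627, 612 and 635 unchanged features, which were 79.5%, 81.8% and 81.1% of the calls. These shares depend on the 200 simulated changes and do not estimate the false share of the real calls, which were 4592 features in WT. The resemblance was drawn separately for each group, with none shared between the groups of a scan period.

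WT arrays with the same replicate number deviated from their group means together, at correlations of 0.333 to 0.532 for the 6 numbers, so the numbers were taken as pairs. The pairing comes from these values alone and not from the labels, and each array's best partner shared its scan period but was not always its own number. The main fit used neither the pairs nor the scan periods. The slide series taken as a block among the alternatives below is the same grouping of arrays as the scan periods. The pair of mutant numbers gave -0.128 and was not taken as paired.

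Alternatives were normexp background correction with an offset of 50, quantile normalization, both together, the authors' series table, no filter and a stricter filter, the median over probes, an intensity trend in the moderation, the groups of each comparison alone, a replicate block, the same with the mutant low CO2 numbers crossed, slide as a random block, the slide series as a fixed block, WT replicates 5 and 6 alone, each slide or scan period that holds more than 1 group, each array left out in turn, a 2-fold threshold, and arrays of a scan period averaged before the fit, also with scan period as a block.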

Results

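Transcript levels were measured in the unicellular cyanobacterium Synechocystis sp. PCC 6803 on strand-specific microarrays. The WT was a glucose-tolerant strain, and the other strain is labelled ΔcyabrB2, a mutant of CyAbrB2 (sll0822), a transcription regulator of the AbrB family. Cultures bubbled with 5% CO2 (high CO2) were sampled before the shift and again 24 h after the change to ambient air with 0.035% CO2 (low CO2). CO2 level and time since resuspension in fresh medium therefore changed together, and no culture stayed at high CO2 for the 24 h. Each CO2 level had 6 WT arrays, called biological replicates in the labels, and 2 mutant arrays, called duplicates. Between 77.7 and 94.1% of the spots on an array were well above background, and no spot was saturated. The 75th percentile of the processed signal was between 896 and 7313 on the WT arrays and between 2780 and 6079 on the mutant arrays. Of the 8427 features tested, 3345 were protein-coding genes, 1658 antisense transcripts, 1848 transcripts internal to genes, 703 untranslated regions (UTRs), 554 other non-coding RNAs and 319 of other kinds.

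The arrays were scanned in 3 periods: WT replicates 1 and 2, WT replicates 3 and 4, and WT replicates 5 and 6 together with all mutant arrays. Across genes, which are not independent replicates, WT arrays of a group correlated at 0.988 to 0.997 within a scan period (6 pairs) and at 0.947 to 0.966 between periods (24 pairs). The 2 mutant pairs correlated at 0.998 to 0.999, and their difference had 1.5 to 1.55 times the spread of repeated spots, against 4.25 to 9.62 times between WT arrays of different periods. The p values therefore measure only the spread between these arrays, which for arrays of the same period may be technical. With WT replicates 5 and 6 alone, each group is 2 arrays of the same slide, and the p values rest on that close spread only. In scan periods 2 and 3 the CO2 levels were on different slides, and in period 3 they were also scanned on different days. Within these periods, and for the whole mutant response, CO2 level cannot be told apart from slide. In period 3 and for the mutant response this also holds for the scan day.

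The targeted gene, sll0822, was measured with 4 probes and did not pass the test between the strains. Its level in the mutant-labelled arrays differed from WT by a log2 fold change of 0.29 at high CO2 (adjusted p = 0.255) and -0.45 at low CO2 (adjusted p = 0.104). The probes moved apart. Probes 1 and 3 differed by -0.27 and -0.15 at high CO2 and by -0.90 and -1.73 at low CO2, while probes 2 and 4 differed by 0.74 and 0.84 and by 0.33 and 0.50. The mean of probes 2 and 4 minus that of probes 1 and 3 lay between -0.19 and 0.10 on the 12 WT arrays and between 0.97 and 1.71 on the 4 mutant-labelled arrays. The files do not give the part of the gene that was replaced, and a probe outside it does not check the label, so the strain is taken from the labels throughout. With quantile normalization the gene was higher in the mutant-labelled arrays at high CO2 (0.83), and with the replicate block it was lower at low CO2 (-0.70). In WT, sll0822 fell at low CO2 by 0.80 on the log2 scale (adjusted p = 0.000204).

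**Figure D1:**
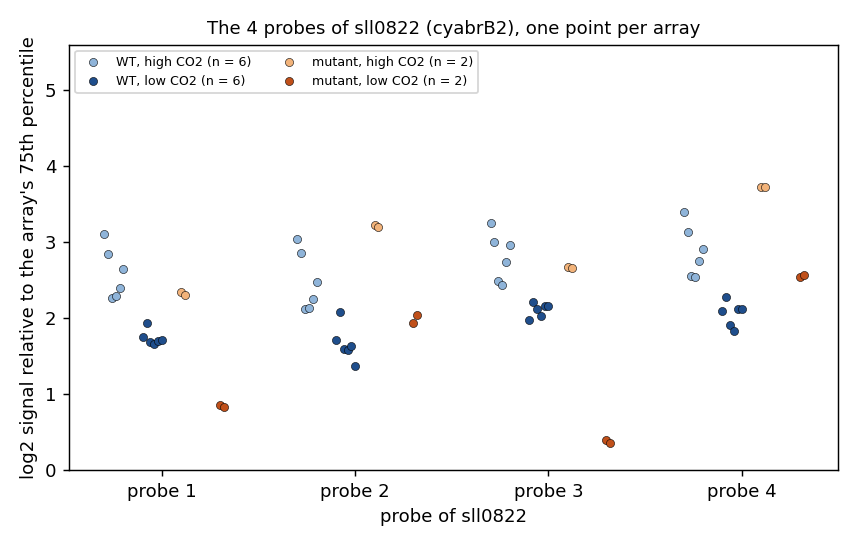
Log2 signal of each of the 4 probes of sll0822 relative to the array's 75th percentile (vertical axis), with a point per array, coloured by strain and CO2 level. In the mutant-labelled arrays probe 3 is lower than in WT at low CO2 by a log2 difference of -1.73, while probes 2 and 4 are higher (0.33 and 0.50).

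The first comparison asked how WT cells respond to 24 h at low CO2. Among protein-coding genes the strongest rise was in the flv4-2 operon, which encodes flavodiiron proteins that protect photosystem II, and in the inducible systems for taking up inorganic carbon. The bicarbonate transporter BCT1 (cmpABCD), the sodium-dependent bicarbonate transporter gene sbtA and the genes of the inducible CO2 uptake complex NDH-1MS (ndhF3, ndhD3, cupA, cupS) all rose. Transcripts for ribosomal proteins, ATP synthase and phycobilisomes fell, as did 12 of 18 genes of nitrogen uptake and assimilation and 7 of 8 heat shock genes. Of 3345 genes, 2018 changed, 811 upwards and 1207 downwards, and 721 of them by at least 2-fold (211 upwards and 510 downwards).

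In WT the 10 members of the inducible carbon uptake list all rose at low CO2, and 10 did when adjusted over the list alone, with a median log2 fold change of 5.88 (camera adjusted p = 3.19e-11, adjusted p = 0.0854 with an estimated correlation). cmpB (slr0041) rose by 7.27 ± 0.61 (n = 6 and 6, adjusted p = 1.75e-07), cmpA (slr0040) by 6.46 ± 0.49 (6.13e-08) and ndhF3 (sll1732) by 6.12 ± 0.14 (1.69e-13). sbtA (slr1512) rose by 4.88 ± 0.14 (2.49e-12). At high CO2 cmpB was well above background on 2 of the 6 WT arrays and cmpA on 5. Within the 3 scan periods the list's median was 6.28, 5.08 and 4.74, with genes not well above background on the high CO2 arrays of a period at their bound. cmpB was among these genes in periods 1 and 2, where it was at least 103-fold and 45.5-fold higher, and it rose by 5.13 in period 3. All 3 genes of the flv4-2 operon rose, also when adjusted over the list alone (3), with a median of 8.35 (camera adjusted p = 2.49e-05, adjusted p = 0.0854 with an estimated correlation). flv4 (sll0217) was not well above background on any WT array at high CO2 and was at least 148-fold higher at low CO2 (adjusted p = 2.49e-12). With flv4 at that bound the operon's median was 8.24. sll0218, a gene of the operon, rose by 8.57 ± 0.18 (5.87e-14), with 4 of 6 high CO2 arrays well above background. With genes at their bound the operon's median within the periods was 8.47, 6.73 and 8.23.

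**Figure D2:**
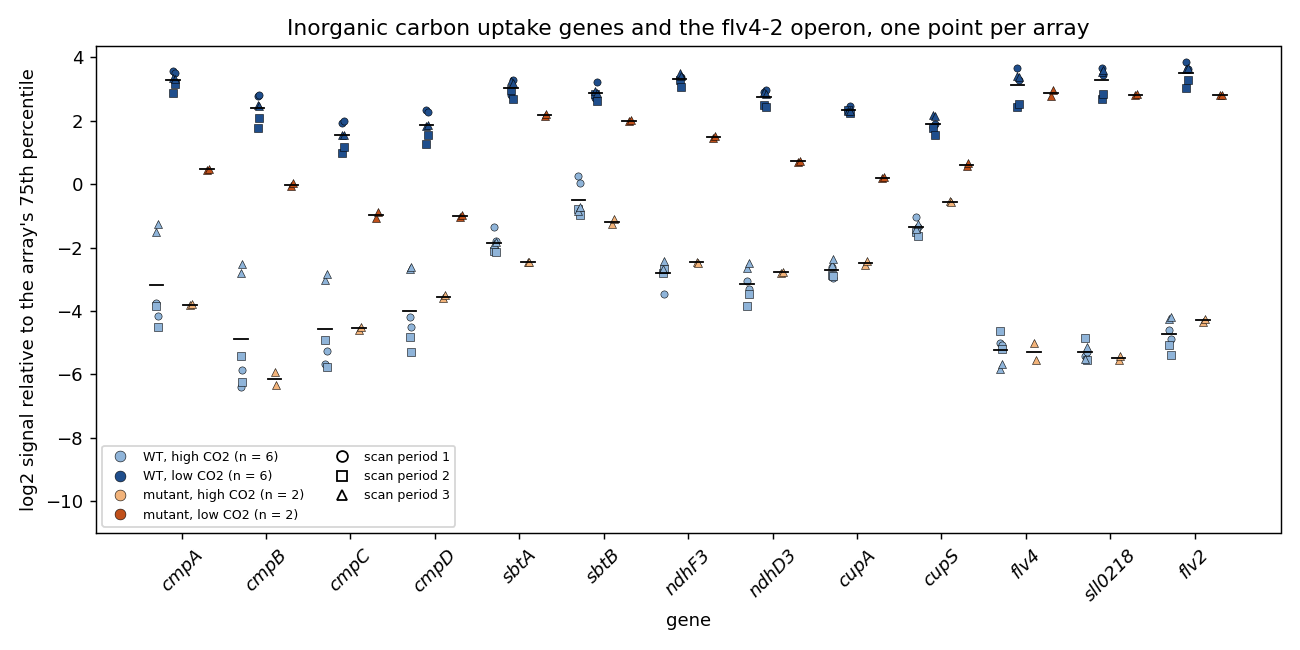
Log2 signal relative to the array's 75th percentile (vertical axis) of the 10 inducible carbon uptake genes and the 3 genes of the flv4-2 operon, with a point per array, shaped by scan period, and a line at each group's mean. cupA is higher at low CO2 by 5.03 in WT and by 2.69 in the mutant-labelled arrays.

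Among the 4 regulators of carbon uptake, 3 rose in WT at low CO2 and 1 did not pass the test (3 adjusted over the list alone, median 1.21, camera adjusted p = 0.0244, adjusted p = 0.164 with an estimated correlation). ndhR (sll1594), the repressor of NDH-1MS and sbtA, rose by 2.91 ± 0.19 (adjusted p = 1.45e-08), and cmpR (sll0030), the activator of the cmp operon, by 2.01 ± 0.18. rbcR (sll0998) rose by 0.41 ± 0.10 (0.00296), a call that ended with the arrays of a scan period averaged. cyabrB1 (sll0359) stood at -0.15. With the replicate block or the slide series as a block the list, at a median of 1.21, was not called. The 4 genes of constitutive carbon uptake fell (4 adjusted over the list alone, median -1.15, camera adjusted p = 0.0244, adjusted p = 0.297 with an estimated correlation), including the bicarbonate transporter gene bicA (sll0834), by 1.64 ± 0.17 on the log2 scale (1.58e-06), and cupB (slr1302), by 1.56 ± 0.10. Of the 12 carboxysome and Rubisco genes, 8 fell and 4 did not pass the test (9 adjusted over the list alone, median -0.56), and the list was not called (camera adjusted p = 0.0982), but it was with normexp.

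Of 15 core subunits of the NDH-1 complex, which carries electrons in respiration and cyclic flow, 12 rose in WT, 1 fell and 2 did not pass the test (14 adjusted over the list alone, median 1.42, camera adjusted p = 1.48e-06, adjusted p = 0.177 with an estimated correlation). ndhA (sll0519) rose by 1.91 ± 0.13, and ndhF1 was the member that fell, by 0.46 on the log2 scale. All 18 type IV pili genes changed, 14 upwards and 4 downwards (18 adjusted over the list alone, median 0.95, camera adjusted p = 0.00057, adjusted p = 0.249 with an estimated correlation), with pilA1 (sll1694), which encodes the main pilin, up by 2.14 ± 0.28. Of 9 sigma factors 7 rose, 1 fell and 1 did not pass the test (8 adjusted over the list alone, median 0.87, camera adjusted p = 0.00676, adjusted p = 0.161 with an estimated correlation). sigI (sll0687) rose by 1.23.

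The 32 measured ribosomal protein genes all fell in WT at low CO2 (32 adjusted over the list alone, median -2.73, camera adjusted p = 1.99e-13, adjusted p = 0.302 with an estimated correlation), with rpl29 (ssl3436) down to -3.25 ± 0.27 (adjusted p = 1.5e-07). All 9 ATP synthase genes fell (9 adjusted over the list alone, median -2.74, camera adjusted p = 7.77e-06, adjusted p = 0.297 with an estimated correlation), atpC (sll1327) by 3.22 ± 0.24 on the log2 scale. Of 18 genes of nitrogen uptake and assimilation, 12 fell, 1 rose and 5 did not pass the test (14 adjusted over the list alone, median -2.45, camera adjusted p = 0.00057, adjusted p = 0.317 with an estimated correlation). The nitrate transporter genes nrtA (sll1450) and nrtB (sll1451) changed by -3.96 ± 0.45 and -3.94 ± 0.33, and glnA (slr1756), glutamine synthetase, by -3.70 ± 0.28 (5.54e-08). Both genes for the glutamine synthetase inactivating factors rose, with a median of 2.19. Both nblA genes, whose products start phycobilisome breakdown, rose with a median of 1.94. These lists were too short to test. Within the 3 scan periods the ribosomal median was -3.43, -2.25 and -2.56. That of ATP synthase was -2.31, -2.83 and -3.04, and that of the nitrogen genes -2.06, -1.88 and -3.52.

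All 13 phycobilisome genes, which encode the light-harvesting antenna, fell in WT (13 adjusted over the list alone, median -1.17, camera adjusted p = 0.00114, adjusted p = 0.386 with an estimated correlation). The allophycocyanin genes apcA (slr2067) and apcB (slr1986) fell by 2.10 ± 0.19 and 2.04 ± 0.24 on the log2 scale, while cpcG2 (sll1471) stood at -3.85 and -0.90 in scan periods 1 and 3 and was at least 39.7-fold lower in period 2. Of 25 photosystem II genes 16 fell, 4 rose and 5 did not pass the test (20 adjusted over the list alone, median -0.73, camera adjusted p = 0.00808, adjusted p = 0.386 with an estimated correlation). psbO (sll0427), of the oxygen-evolving complex, fell by 2.19 ± 0.21, and psbA1 (slr1181), psbA2, psbA3 and psbD2, which encode reaction centre proteins, rose. Of 8 genes for the cytochrome b6f complex and electron carriers 5 fell and 3 did not pass the test (5 adjusted over the list alone, median -1.44, camera adjusted p = 0.0244, adjusted p = 0.317 with an estimated correlation), including the ferredoxin gene petF (ssl0020), by 2.38 ± 0.21. Of 8 heat shock genes 7 fell and 1 did not pass the test (7 adjusted over the list alone, median -1.26, camera adjusted p = 0.0323, adjusted p = 0.484 with an estimated correlation), with the chaperonin genes groES (slr2075) and groEL2 (sll0416) at -3.28 ± 0.39 and -3.23 ± 0.37. Of 11 chlorophyll synthesis genes 8 fell and 3 did not pass the test (8 adjusted over the list alone, median -0.53, camera adjusted p = 0.0273, adjusted p = 0.317 with an estimated correlation), with por (slr0506) at -1.73 ± 0.21. Within the periods the phycobilisome median was -0.97, -1.73 and -1.10. Photosystem II had medians of -0.58, -1.12 and -0.88, and the electron carriers of -1.03, -1.65 and -1.55. The heat shock genes had medians of -1.43, -1.11 and -1.73, and chlorophyll synthesis of -0.34, -0.51 and -0.59.

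The largest fall in WT among all genes was in ssl2384, by 4.48 ± 0.36 on the log2 scale (adjusted p = 1.04e-07, 3 of 6 low CO2 arrays well above background). Outside protein-coding genes, 629 antisense transcripts rose and 173 fell, and 169 non-coding RNAs rose and 101 fell. The largest rises outside genes were those of us29-0-x, by 8.80 ± 0.96 (adjusted p = 2.29e-06; 10.57, 10.08 and 5.76 within the scan periods), slr0040-int1, by 7.91 ± 0.69 (2.77e-07, 2 of 6 high CO2 arrays well above background), and NC-1136, by 7.10 ± 0.22 (3.29e-12, 4 of 6). The largest falls were those of slr1535-5'UTR, by 5.43 ± 0.31 on the log2 scale (4.36e-09, 1 of 6 low CO2 arrays well above background), and NC-240, by 4.80 ± 0.55. With the arrays of a scan period averaged before the fit, 804 genes changed in WT, 237 upwards and 567 downwards. That averaging kept all calls of inducible carbon uptake, flv4-2, ribosomal and ATP synthase genes. It ended most calls of sigma factor, carboxysome and chlorophyll synthesis genes and some of phycobilisome genes, at the same fold changes. Quantile normalization ended the list calls of the electron carriers (median -1.24) and of chlorophyll synthesis (-0.49). The series table (-1.18) and normexp with quantile normalization (-1.23) ended that of the electron carriers.

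The second comparison set the mutant-labelled arrays against WT at high CO2. In the mutant-labelled arrays, genes of the bidirectional hydrogenase, 4 of 8 heat shock genes, the iron stress gene isiA, a pilin gene and psbA1 were higher than in WT. Many genes of photosystem II, photosystem I, the phycobilisome, the cytochrome b6f complex, ATP synthase and chlorophyll synthesis were lower. After scaling, the 99th percentile of the log2 probe signals was 4.21 on both mutant arrays and 4.67 to 5.24 on the WT arrays. The brightest probes thus read lower on these mutant arrays, and how far this bears on lists of bright genes was not tested. Camera called no shift of the inducible carbon uptake genes at high CO2, but against WT replicates 5 and 6 of the same scan period the cmp genes were lower. On those WT arrays the cmp genes stood higher than on the other WT arrays at high CO2. Of 3345 genes 1459 differed, 738 higher and 721 lower, and 616 of them by at least 2-fold (389 higher and 227 lower). With normexp 1524 differed, 637 higher and 887 lower.

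All 5 hydrogenase genes were higher in the mutant-labelled arrays at high CO2 (5 adjusted over the list alone, median 2.15, camera adjusted p = 0.000552, adjusted p = 0.377 with an estimated correlation), hoxF (sll1221) by 2.50 ± 0.42 and hoxU (sll1223) by 2.30 ± 0.25 (adjusted p = 1.16e-05, n = 2 and 6). Of 8 heat shock genes 4 were higher and 4 did not pass the test (4 adjusted over the list alone, median 1.04, camera adjusted p = 0.0469, adjusted p = 0.704 with an estimated correlation). hspA (sll1514), a small heat shock protein, was higher by 3.38 ± 0.41 (2.96e-05) and htpG (sll0430) by 2.57 ± 0.40. isiA (sll0247), the chlorophyll-binding protein of iron-starved cells, was higher by 4.60 ± 0.35 (4.06e-07, 2 of 6 WT arrays well above background), the pilin gene pilA2 (sll1695) by 4.16 ± 0.43 (7.24e-06) and psbA1 by 2.61 ± 0.21 (5.59e-07). Among genes without a symbol, ssr1966 was higher by 5.01 ± 0.47 (2.6e-06, 4 of 6 WT arrays well above background) and slr1185 by 4.42 ± 0.30 (2e-07). Both nblA genes were higher, with a median of 2.75.

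Of the 25 photosystem II genes 19 were lower in the mutant-labelled arrays at high CO2, 1 (psbA1) was higher and 5 did not pass the test (22 adjusted over the list alone, median -1.09, camera adjusted p = 1.81e-06, adjusted p = 0.377 with an estimated correlation). psbO differed by -1.99 ± 0.30 (adjusted p = 0.00017). Of 12 photosystem I genes 6 were lower and 6 did not pass the test (9 adjusted over the list alone, median -1.33, camera adjusted p = 0.0124, adjusted p = 0.750 with an estimated correlation), with psaD (slr0737) at -1.64 ± 0.42 (0.00717). Of 13 phycobilisome genes 9 were lower and 4 did not pass the test (12 adjusted over the list alone, median -1.25, camera adjusted p = 0.000849, adjusted p = 0.538 with an estimated correlation). Of 8 genes for cytochrome b6f and electron carriers 7 were lower and 1 did not pass (8 adjusted over the list alone, median -1.04, camera adjusted p = 0.00192, adjusted p = 0.377 with an estimated correlation), with petH (slr1643), which makes NADPH from reduced ferredoxin, at -1.46 ± 0.22. All 9 ATP synthase genes were lower (9 adjusted over the list alone, median -1.03, camera adjusted p = 0.00192, adjusted p = 0.538 with an estimated correlation). Of 11 chlorophyll synthesis genes 8 were lower and 3 did not pass (9 adjusted over the list alone, median -0.98, camera adjusted p = 0.000849, adjusted p = 0.377 with an estimated correlation), with por at -1.97 ± 0.29.

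Of 18 nitrogen genes 7 were lower in the mutant-labelled arrays at high CO2 and 11 did not pass the test (7 adjusted over the list alone, median -0.65, camera adjusted p = 0.00259, adjusted p = 0.538 with an estimated correlation); the ammonium transporter gene amt1 (sll0108) differed by -2.04 ± 0.32. Of 12 carboxysome and Rubisco genes 5 were lower and 7 did not pass (5 adjusted over the list alone, median -0.50, camera adjusted p = 0.00192, adjusted p = 0.538 with an estimated correlation). rbcL (slr0009), the large subunit of Rubisco, differed by -1.32 ± 0.19 (adjusted p = 8.95e-05). Of 15 NDH-1 core genes 7 were lower and 8 did not pass (7 adjusted over the list alone, median -0.38, camera adjusted p = 0.00655, adjusted p = 0.538 with an estimated correlation). Of the 10 inducible carbon uptake genes cupS (sll1735) was higher by 0.81 ± 0.18 (0.00282), sbtA differed by -0.60 (0.0319) and 8 did not pass the test (1 adjusted over the list alone), with a median of 0.12, a mean of -0.10 and camera's direction upwards (camera adjusted p = 0.957). The median was -0.11 with normexp. Against WT replicates 5 and 6 alone it was -0.50, not called, while cmpA (-2.41), cmpB (-3.48, 1 of 2 mutant arrays well above background), cmpC (-1.62), cmpD (-0.90), sbtB (-0.40) and ndhD3 (-0.21) were lower. On those WT arrays the cmp genes stood above their levels on the other WT arrays at high CO2. The log2 level of cmpA was -1.52 and -1.26 there and -4.50 to -3.75 on WT replicates 1 to 4. On the mutant arrays it was -3.81 and -3.78. The 3 genes of the flv4-2 operon did not pass (0 adjusted over the list alone and 0 at an unadjusted p under 0.05 in limma), with sll0218 at -0.19 and flv2 (sll0219) at 0.44. No fold is given for flv4, which was not well above background on any WT array there. Of the 4 carbon regulators rbcR was lower, at -1.53 ± 0.14 (2.47e-06), and 3 did not pass the test. The largest falls without a symbol were slr1761, by 2.55 ± 0.27 on the log2 scale (9.09e-06), and slr2043, by 2.35.

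With 1 mutant array left out at high CO2 the count fell from 1459 to 773 or 803, with slide as a random block to 551, and with the arrays of a scan period averaged to 93 (89 higher and 4 lower). That averaging kept the calls of 2 of the 5 hydrogenase genes, hspA and psbA1. It ended those of all photosystem I, phycobilisome, electron carrier, ATP synthase and chlorophyll synthesis genes and of the photosystem II genes other than psbA1, with the same fold changes. The calls of all nitrogen, carboxysome and Rubisco, NDH-1 core and inducible carbon uptake genes and of rbcR ended too. Against WT replicates 5 and 6 alone the count of differing genes was 2616. Quantile normalization ended the calls of photosystem I, the electron carriers, ATP synthase and the carboxysome genes, and normexp with quantile normalization, the series table and the slide series as a block each that of photosystem I. Against WT replicates 5 and 6 alone, from the same scan period, the hydrogenase median was 1.71, that of photosystem II -0.92, of the phycobilisome -0.62, of photosystem I -0.44, of ATP synthase -1.25 and of the heat shock genes 0.41, the last no longer called. The heat shock genes were not called with the replicate block (0.86), the slide series as a block (0.80) or the groups of this comparison alone (1.04) either. The 32 ribosomal protein genes (0 passed, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 in limma) had a median of -0.35 and were not called (camera adjusted p = 0.0634), but they were with the replicate block (-0.54), the slide series as a block (-0.63), WT replicates 5 and 6 alone (-0.55) and arrays of a scan period averaged (-0.35), and their median was 0.18 with quantile normalization.

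The third comparison set the strains against each other at low CO2. The inducible carbon uptake genes were all lower in the mutant-labelled arrays, as were most NDH-1 core genes and all ATP synthase genes. The genes of the flv4-2 operon did not pass the test against all WT arrays and were lower against WT replicates 5 and 6 of the same scan period. The hydrogenase genes and 5 of 8 heat shock genes were higher. Of 3345 genes 1097 differed, 653 higher and 444 lower, and 514 of them by at least 2-fold (392 higher and 122 lower). With normexp 1247 differed and the split was 517 higher and 730 lower.

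All 10 inducible carbon uptake genes were lower in the mutant-labelled arrays at low CO2 (10 adjusted over the list alone, median -2.08, camera adjusted p = 3.67e-06, adjusted p = 0.373 with an estimated correlation). cmpD (slr0044) differed by -2.85 ± 0.57 (adjusted p = 0.00185, n = 2 and 6), cmpA by -2.83 ± 0.69 (0.00668), cupA (sll1734) by -2.12 ± 0.15 (3.26e-07), ndhF3 by -1.84 ± 0.20 (1.33e-05) and sbtA by -0.85 ± 0.20 (0.00613). On the slide that held both strains at low CO2 the list's median was -2.13. cmpB stood at -2.42 ± 0.86 (0.0492) and did not pass with the replicate block (-1.99). The 3 genes of the flv4-2 operon did not pass the test (0 adjusted over the list alone and 1 at an unadjusted p under 0.05 in limma, median -0.47, camera adjusted p = 0.373). Genes flv4 (-0.53), sll0218 (-0.74) and flv2 (-0.85) passed as lower against WT replicates 5 and 6 alone, where each group is 2 arrays of the same slide. The list, at a median of -0.74, was not called there. Of 15 NDH-1 core genes 10 were lower and 5 did not pass (11 adjusted over the list alone, median -1.02, camera adjusted p = 3.67e-06, adjusted p = 0.373 with an estimated correlation), with ndhE (sll0522) at -1.52 ± 0.14 (2.73e-06) and ndhB (sll0223) at -1.51 ± 0.18. All 9 ATP synthase genes were lower (9 adjusted over the list alone, median -1.34, camera adjusted p = 8.52e-05, adjusted p = 0.611 with an estimated correlation), atpG (sll1323) and atpD at -1.42 each.

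At low CO2 the 5 hydrogenase genes were all higher in the mutant-labelled arrays (5 adjusted over the list alone, median 1.94, camera adjusted p = 0.000322, adjusted p = 0.373 with an estimated correlation), with hoxU higher by 2.21 ± 0.25 (adjusted p = 1.73e-05). Of 8 heat shock genes 5 were higher and 3 did not pass (8 adjusted over the list alone, median 1.47, camera adjusted p = 0.0205, adjusted p = 0.611 with an estimated correlation), hspA by 3.70 ± 0.41 (1.46e-05). psbA1 was higher by 2.34 ± 0.21. Both nblA genes were higher, with a median of 2.58. ssr1966 was higher by 6.50 ± 0.47 (3.29e-07, 3 of 6 WT arrays well above background) and slr1185 by 5.12 ± 0.30 (1.21e-07), while slr0616 differed by -2.37 ± 0.16 (1.6e-07) and slr1763 by -2.32 ± 0.20 (1.84e-06). Of 11 chlorophyll synthesis genes 5 were lower and 6 did not pass (9 adjusted over the list alone, median -0.60, camera adjusted p = 0.00414, adjusted p = 0.373 with an estimated correlation). Of 18 nitrogen genes 5 were lower and 13 did not pass (6 adjusted over the list alone, median -0.44, camera adjusted p = 0.00867, adjusted p = 0.611 with an estimated correlation), with the nitrite reductase gene nirA (slr0898) at -1.96 ± 0.50 (0.00842). Against WT replicates 5 and 6 alone nirA stood at -0.87. Of 25 photosystem II genes 9 were lower, psbA1 was higher and 15 did not pass (11 adjusted over the list alone, median -0.40, camera adjusted p = 0.00867, adjusted p = 0.611 with an estimated correlation). Of 12 carboxysome and Rubisco genes 5 were lower and 7 did not pass (5 adjusted over the list alone, median -0.32, camera adjusted p = 0.0185, adjusted p = 0.611 with an estimated correlation).

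**Figure D3:**
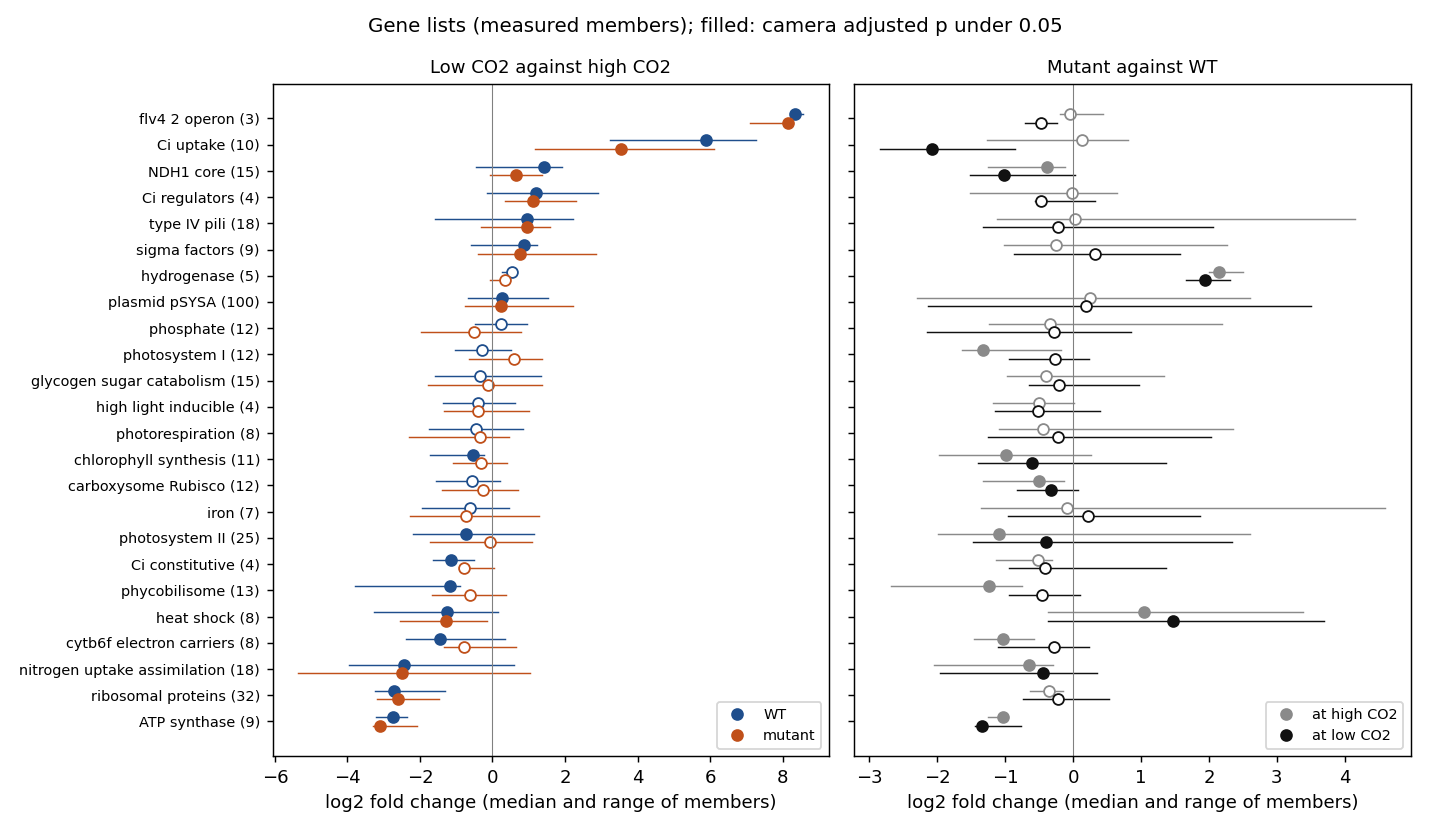
Median (point) and range (line) of the log2 fold changes of the measured members of each gene list, with the number of members in brackets; low against high CO2 on the left and mutant against WT on the right, filled where the camera adjusted p was under 0.05. The inducible carbon uptake list lies at 5.88 in WT and 3.54 in the mutant on the left, and at 0.12 (high CO2) and -2.08 (low CO2) on the right.

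Without either of the mutant arrays at low CO2 the count of 1097 fell to 552 or 537, and with arrays of a scan period averaged to 86 (79 higher and 7 lower). That averaging kept the calls of 2 of the 10 inducible carbon uptake genes, cupA and ndhF3, and ended those of the other 8 (8 of the 10 had an unadjusted p under 0.05). It also ended those of all NDH-1 core, ATP synthase, hydrogenase, nitrogen, chlorophyll synthesis and carboxysome genes, with the same fold changes. Most calls of photosystem II and heat shock genes ended too, but not those of psbA1 and hspA. The count of differing genes was 1681 with the replicate block, 2250 with slide as a random block, 1657 with the slide series as a block, 2473 against WT replicates 5 and 6 alone and 2383 on the slide with both strains. Normexp, quantile normalization, both together and the series table each ended the calls of the photosystem II list (medians -0.32, -0.22, -0.18 and -0.17) and the carboxysome list (-0.32, -0.28, -0.28 and -0.21). The slide series as a block ended those of the carboxysome (-0.34), photosystem II (-0.27) and heat shock (1.27) lists. With the replicate block the heat shock list (median 1.23) was not called, and the phycobilisome list (-0.58, against -0.46 without the block) and the ribosomal list (-0.43, against -0.22) were. The ribosomal list was also called with the slide series as a block (-0.48) and with WT replicates 5 and 6 alone (-0.62), and so were the electron carriers (-0.52 and -0.51). Against WT replicates 5 and 6 alone the median of the NDH-1 core genes was -1.02, of ATP synthase -1.13, of hydrogenase 1.61, of heat shock 1.91, of photosystem II -0.39, of nitrogen genes -0.36, of chlorophyll synthesis -0.32 and of carboxysome genes -0.26, the last 2 no longer called.

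The fourth comparison was the low CO2 response within the mutant-labelled arrays. Their CO2 levels were on different slides scanned on different days, so CO2 level cannot be told apart from slide or scan day. The flv4-2 operon, the inducible carbon uptake genes and 3 of 9 sigma factor genes rose, and the ribosomal protein and ATP synthase genes and 12 of 18 nitrogen genes fell. Of 3345 genes 1063 changed, 406 upwards and 657 downwards, and 593 by at least 2-fold (222 upwards and 371 downwards). Across genes, which are not independent replicates, this response correlated with that of WT at r = 0.846 (Spearman's rho 0.801), with a slope of 0.80. The mutant response set against WT within the 3 scan periods gave 0.827, 0.733 and 0.855. In both strains 306 genes rose (98.4 for independent lists), 604 fell (237 for independent lists) and 6 changed in opposite directions.

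In the mutant-labelled arrays the 3 genes of the flv4-2 operon rose (3 adjusted over the list alone, median 8.15, camera adjusted p = 2.8e-07, adjusted p = 0.0319 with an estimated correlation), flv4 by 8.15 ± 0.43 (adjusted p = 1.39e-08, n = 2 and 2). The 10 inducible carbon uptake genes rose (10 adjusted over the list alone, median 3.54, camera adjusted p = 2.09e-10, adjusted p = 0.0718 with an estimated correlation), sbtA by 4.62 ± 0.25, ndhF3 by 3.95 ± 0.25 and cmpD by 2.55 ± 0.70 (0.0142). Of 4 carbon regulators 3 rose and 1 did not pass (3 adjusted over the list alone, median 1.13, camera adjusted p = 0.0054, adjusted p = 0.0718 with an estimated correlation). Of 15 NDH-1 core genes 8 rose and 7 did not pass (10 adjusted over the list alone, median 0.65, camera adjusted p = 0.000106, adjusted p = 0.249 with an estimated correlation). Of 18 type IV pili genes 11 rose and 7 did not pass (11 adjusted over the list alone, median 0.95, camera adjusted p = 3.99e-05, adjusted p = 0.157 with an estimated correlation). Of 9 sigma factors 3 rose and 6 did not pass (4 adjusted over the list alone, median 0.77, camera adjusted p = 0.00725, adjusted p = 0.125 with an estimated correlation), with sigI up by 2.86 ± 0.21.

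All 32 ribosomal protein genes fell in the mutant-labelled arrays at low CO2 (32 adjusted over the list alone, median -2.60, camera adjusted p = 1.29e-16, adjusted p = 0.249 with an estimated correlation), as did all 9 ATP synthase genes (9 adjusted over the list alone, median -3.09, camera adjusted p = 2.27e-08, adjusted p = 0.194 with an estimated correlation). Of 18 nitrogen genes 12 fell, 2 (glnB and gltB) rose and 4 did not pass (14 adjusted over the list alone, median -2.49, camera adjusted p = 0.000611, adjusted p = 0.366 with an estimated correlation). nrtA stood at -5.36 ± 0.77 (adjusted p = 0.00021), glnA at -4.15 ± 0.48 and nirA at -4.09 ± 0.61. Of 8 heat shock genes 4 fell and 4 did not pass (4 adjusted over the list alone, median -1.29, camera adjusted p = 0.0463, adjusted p = 0.643 with an estimated correlation), and the slide series as a block ended this call at the same median. With the mutant groups alone or WT replicates 5 and 6 alone, photosystem I (0.59) and the phycobilisome (-0.63) were called. Outside genes us29-0-x rose by 10.57 ± 1.66 (0.000428, 1 of 2 high CO2 arrays well above background), and slr0040-int1 was at least 36.2-fold higher. Both glutamine synthetase inactivating factor genes rose (median 2.79), as did both nblA genes (median 1.77). The count of 1063 was 585, 597, 600 or 590 without mutant array 1 or 2 at high CO2 or 1 or 2 at low CO2, 638 with slide as a random block and 7 with the arrays of a scan period averaged: the 3 flv4-2 genes, ndhF3, cupA, sbtA and sigI. It was 1692 with the replicate block, 1896 with the slide series as a block, 2592 with WT replicates 5 and 6 alone and 2723 with the mutant arrays alone.

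The last comparison asked whether the response to low CO2 differed between the strains. As a group the inducible carbon uptake genes rose less in the mutant-labelled arrays than in WT (adjusted p = 0.225 with an estimated correlation), with all 4 genes of NDH-1MS past the test. The NDH-1 core genes as a group also rose less (adjusted p = 0.655 with an estimated correlation), with 3 of 15 past the test. Photosystem II genes as a group had a less negative response in the mutant-labelled arrays (adjusted p = 0.491 with an estimated correlation), although no member passed the test over all features. The 99th percentile of the scaled log2 probe signals was 4.21 on the mutant arrays at high CO2 and 5.01 to 5.13 at low CO2. On the WT arrays it was 4.67 to 5.24 and 5.08 to 5.57. How far this bears on the response differences of bright genes was not tested. Of 3345 genes 88 differed in response, 51 with a higher and 37 with a lower value in the mutant-labelled arrays, 72 of them by at least 2-fold (45 higher and 27 lower).

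Of the 10 inducible carbon uptake genes 5 had a lower response in the mutant-labelled arrays and 5 did not pass the test (6 adjusted over the list alone, median response difference -2.19, camera adjusted p = 5.81e-10, adjusted p = 0.225 with an estimated correlation). The response differences were -2.34 ± 0.22 for cupA (adjusted p = 8.67e-05), -2.38 ± 0.40 for ndhD3 (sll1733, 0.00621), -2.18 ± 0.29 for ndhF3 (0.00137), -2.08 ± 0.26 for cupS (0.000896) and -3.31 ± 0.81 for cmpD (0.0459). cmpA (-2.20, 0.292), cmpB (-1.15, 0.742), cmpC (slr0043, -2.53, 0.198), sbtA (-0.26, 0.753) and sbtB (slr1513, -0.19, 0.886) did not pass. Against WT replicates 5 and 6 alone, from the scan period of the mutant-labelled arrays, the list's median was -1.42. The NDH-1MS genes and cmpD then stood at -2.33 to -1.95, and the other genes at -0.90 (cmpC) to 0.99 (cmpB). Of 15 NDH-1 core genes 3 had a lower response and 12 did not pass (7 adjusted over the list alone, median -0.50, camera adjusted p = 0.000632, adjusted p = 0.655 with an estimated correlation), among them ndhE at -1.31 ± 0.20 (0.00304) and ndhG (sll0521) at -1.11 ± 0.18 (0.00513). The 3 flv4-2 genes did not pass (1 adjusted over the list alone, median -0.28, camera adjusted p = 0.210). Against WT replicates 5 and 6 alone sll0218 (-0.58) and flv2 (-0.77) did, and the list was called with a lower response (median -0.77). flv4, not well above background on those WT arrays at high CO2, has no fold there, and with it at its bound the median was -0.58.

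**Figure D4:**
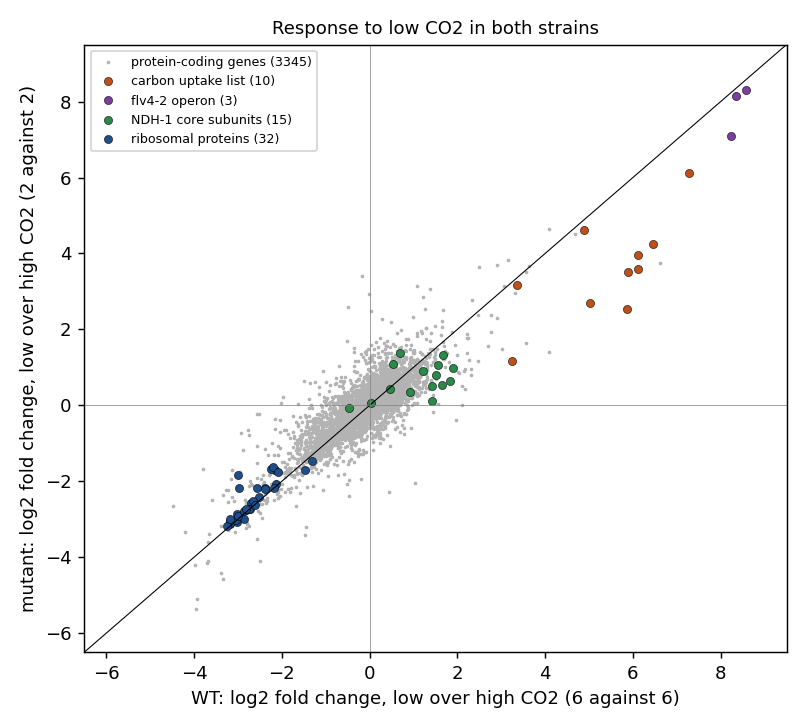
Log2 fold change from high to low CO2 in WT (horizontal axis) and in the mutant-labelled arrays (vertical axis) for 3345 protein-coding genes, with 4 gene lists coloured and a line of equal change. The 32 ribosomal protein genes lie near the line (medians -2.73 and -2.60), and the 10 carbon uptake genes lie below it (medians 5.88 and 3.54).

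Of the 25 photosystem II genes none passed the test of the response difference over all features, and 13 did when adjusted over the list alone and 14 at an unadjusted p under 0.05 in limma (median 0.67, camera adjusted p = 1.99e-06, adjusted p = 0.491 with an estimated correlation). The 13 phycobilisome genes had a median difference of 0.78 (0 passed, 3 adjusted over the list alone and 3 unadjusted, camera adjusted p = 0.00164, adjusted p = 0.790 with an estimated correlation). For the 12 photosystem I genes it was 0.79 (0 passed, 0 adjusted over the list alone and 1 unadjusted, camera adjusted p = 0.0315, adjusted p = 0.871 with an estimated correlation). For the 8 genes of cytochrome b6f and electron carriers it was 0.51 (0 passed, 0 adjusted over the list alone and 3 unadjusted, camera adjusted p = 0.0140, adjusted p = 0.655 with an estimated correlation). isiA had a response difference of -2.73 ± 0.49 (adjusted p = 0.0104), slr0616 of -2.69 ± 0.22 (3.82e-05), rbcR of 0.96 ± 0.20 (0.0221) and slr1262 of 2.28 ± 0.30 (0.00135). Leaving out a mutant array reduced the 88 genes to between 14 and 18, and leaving out WT low CO2 replicate 2 raised them to 139. Averaging the arrays of a scan period left 0 in limma's test (83 at an unadjusted p under 0.05, against 518 before averaging), so the calls of the 5 carbon uptake and 3 NDH-1 core genes ended too, with 5 and 3 members of these lists at an unadjusted p under 0.05. The replicate block gave 396 (228 higher and 168 lower, among them all 88), the slide series as a block 648, and 173 differed in the authors' series values. Against WT replicates 5 and 6 alone the median was -0.51 for NDH-1 core genes, 0.57 for photosystem II, 0.70 for the phycobilisome, 0.73 for photosystem I and 0.62 for the electron carriers. Quantile normalization, alone or with normexp, and the authors' series values each ended the calls of the phycobilisome, photosystem I and electron carrier lists. ATP synthase was called with quantile normalization (-0.75). With WT replicates 5 and 6 alone carboxysome (0.84), nitrogen (0.57), heat shock (0.57), glycogen and sugar breakdown (0.41) and chlorophyll synthesis genes (0.40) were called.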

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

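The tests of the scan period, the groupings that keep a scan period together and the tests of the sll0822 probes were chosen after the results were seen, and so were the scan periods averaged or taken alone; the other tests were not.

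Other groupings of the arrays rarely gave changes like those between CO2 levels in WT. With the 12 WT arrays fitted alone, the real grouping gave 1870 changed genes, and 1 of 100 groupings drawn from the 462 possible, the real one, gave as many. The highest other gave 839 and parted 4 of the 6 replicate pairs; 94 of the others gave 0, and so did the 4 drawn others that part all pairs. Chance can be excluded for this count if the 12 arrays are taken as independent. With the 2 arrays of a CO2 level and scan period kept together, 1 of 10 groupings, the real one, gave 1870 genes and the highest other gave 178, and 10 groupings are too few for a share under 0.05. No such groupings were run for the comparisons with 2 mutant arrays.

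The inducible carbon uptake list had a median response difference between mutant and WT of -2.19 (adjusted p = 0.225 with an estimated correlation), and 88 genes differed in response. Camera at a correlation of 0.01 also called lists of NDH-1 core genes (-0.50), photosystem II (0.67), photosystem I (0.79), the phycobilisome (0.78) and electron carriers (0.51). None of these was called with an estimated correlation (adjusted p = 0.655, adjusted p = 0.491, adjusted p = 0.871, adjusted p = 0.790 and adjusted p = 0.655 with an estimated correlation, in that order). In the fit of all arrays only the NDH-1 list had members that passed, 3 of 15. With WT replicates 5 and 6 alone members of each of the other lists passed too. Against WT replicates 5 and 6 of the same period the response differences of the NDH-1MS genes stayed at -2.33 to -1.95. For those genes this argues against a difference between scan periods as the whole cause. The list's median was then -1.42, but cmpA (-0.45), cmpB (0.99), cmpC (-0.90), sbtA (-0.44) and sbtB (-0.51) lay above it and cmpD (-1.95) below. For the genes above it the scan period is not excluded. The list's median after normexp was -1.96, which argues against background left in the processed signals as the whole cause of that median. The NDH-1MS genes were well above background on all arrays. Each cmp gene was not on some of the WT arrays at high CO2, and for the cmp genes background is not excluded. A wider loss of low CO2 induction stays open. The other 37 genes that rose at least 4-fold in WT had a median response difference of -0.82 (quartiles -1.31 and -0.18), with 30 of them negative and 7 past the threshold. They were chosen for their rise in WT, which is subtracted in the difference, so the choice itself pushes these values down. That a missing regulator weakens induction of the carbon uptake genes stays a hypothesis that these data do not separate from a general difference of the mutant cultures.

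The 4 probes of sll0822 changed unequally in the mutant-labelled arrays. The lowest contrast between probes on a mutant-labelled array exceeded the highest on a WT array by 0.87. The probes were grouped by their direction between the strains on these same arrays, which favours such a gap. The contrast therefore cannot by itself exclude WT RNA under a mutant label. The scan period alone does not give the contrast, since the 4 WT arrays of the period with the mutant arrays reached only -0.055. A gene that is partly replaced, with transcripts over the remaining part, may give such a contrast, but the positions of the probes and of the replaced part are not in the files, and this was not tested.

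Antisense transcripts stood higher at low CO2 than protein-coding genes. Against genes matched on mean signal their median log2 fold change was higher by 0.44 in WT (95% interval 0.37 to 0.48 over resampled features). At this scaling that argues against a rise of dim features whatever their strand as the whole cause. The interval holds the arrays fixed, so it does not measure the spread between arrays or cultures. No matched difference was taken with the other scalings. The mutant-labelled arrays argue against a higher background on the WT low CO2 arrays as the whole cause. There the same difference was 0.30 (0.24 to 0.37, again over resampled features). The scaling stays open: the difference without matching, 0.53, was 0.35 with normexp, 0.51 with quantile normalization, 0.32 with both and 0.16 in the series table, the lowest. No biological explanation was tested.

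Of the 88 genes whose response differed between the strains by limma's test, those that the rule for named genes gave were isiA (-2.73), ndhI (-1.20), ndhG (-1.11), ndhE (-1.31), rbcR (0.96), ndhF3 (-2.18), ndhD3 (-2.38), cupA (-2.34), cupS (-2.08) and cmpD (-3.31). Those without a symbol were sll1250 (2.19), sll1626 (2.23), sll2507 (3.09), slr0616 (-2.69), slr1259 (2.12), slr1261 (2.09), slr1262 (2.28), slr1452 (-3.08), ssr1527 (2.20) and ssr1853 (2.45). Other features were sll0834-5'UTR (4.92), sll1362-as1 (3.80), slr0044-int1 (-3.22), slr0442-5'UTR (-2.45), slr0616-int1 (-2.70) and slr1032-int2 (4.48). In at least 1 group sll2507, sll0834-5'UTR, sll1362-as1 and slr1032-int2 were not well above background on any array, so their values are no folds. Among the genes outside the rule, sigI (1.63) and sll0823 (-1.94) were chosen after their values were seen.

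Among the named features, an array stood far from the others of its group in 3 of 70 at high CO2 and 5 of 66 at low CO2 in WT. For independent arrays chance gives about 1 in 20, and arrays of a scan period resembled each other, so that rate may not hold. All of the arrays were WT replicate 1 or 2, which at each CO2 level lay on different slides. At high CO2 the outlying values were the log2 levels of sll0450 on WT replicate 1 (-5.47, nearest other -4.40), ndhF3 on replicate 2 (-3.45, nearest -2.80) and slr1262 on replicate 2 (-1.07, nearest -1.74). At low CO2 they were NC-240 on replicate 1 (-6.06, nearest -3.22) and, on replicate 2, sll0822 (2.13, nearest 1.90), hspA (0.44, nearest -0.67), slr1763 (-1.99, nearest -2.57) and ssl2384 (-2.92, nearest -4.71).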

How the results depend on the processing

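The averaging of arrays of a scan period, the crossed replicate numbers and the fits within a scan period were chosen after the data were seen, the other alternatives before. WT low against high CO2 changed 1596 to 2574 genes in the alternatives that stayed within 1.5 times of 2018, apart from leaving out single arrays; by the same measure, at high CO2 the strains differed in 1398 to 2038 genes, at low CO2 in 956 to 1284, the mutant response was 1039 to 1232 genes and the response difference 72 to 111. The correlation of the strains' responses stayed between 0.815 and 0.867. Within scan periods 1, 2 and 3 alone WT changed 1799, 1717 and 2531 genes. In periods 2 and 3 the CO2 levels were on different slides, and in period 3 also scanned on different days. At least 2-fold, the counts were 721 for WT, 616 and 514 for mutant against WT at high and low CO2 and 593 for the mutant response, fewer because fewer genes meet both criteria. Of 53 list shifts camera called at a correlation of 0.01, 1 held with an estimated correlation, the flv4-2 operon in the mutant. Unless a cause is named, the cause was not tested.

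The level of sll0822 in mutant against WT passed the test at high CO2 with quantile normalization (0.83), normexp and quantile normalization (0.82), the series table (0.78) and WT replicates 5 and 6 alone (0.34). At low CO2 it did with the groups of the comparison alone (-0.45), the replicate block (-0.70, also with crossed numbers), slide as a random block (-0.42), the slide series as a block (-0.42) and WT replicates 5 and 6 alone (-0.43). The series table gave 173 genes with a response difference, and the mutant groups alone gave 2723 genes for the mutant response. Normexp shifted the median log2 fold change of all genes between the strains at low CO2 from -0.003 to -0.14, and the split from 653 higher and 444 lower to 517 and 730.

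With the replicate block the strains differed at low CO2 in 1681 genes, the mutant response had 1692 and the response difference 396. This block sets mutant numbers 1 and 2 beside WT numbers 1 and 2 of another scan period. Of 348 gene results it made 23 pass and 1 fail, and apart from these, sll0822 and the lists of carbon regulators and hydrogenase (WT), heat shock and ribosomal genes (high CO2), heat shock, phycobilisome and ribosomal genes (low CO2) and phosphate (response difference) it changed no other call. Replicate block with the mutant low CO2 numbers crossed gave 1677, 1691 and 387. Slide as a random block (correlation 0.898) gave 551 at high CO2, 2250 at low CO2, 638 for the mutant response and 42 for the response difference; the slide series as a block gave 1657 at low CO2, 1896 and 648. WT replicates 5 and 6 alone gave 2616, 2473, 2592 and 1809, and the slide with both strains at low CO2 2383. With WT replicates 5 and 6 alone the p values measure only the spread within slides, not between cultures. With these WT arrays some values, uncalled before, changed sign and passed the test: ndhD3 (-0.21), cmpC (-1.62) and cmpD (-0.90) between strains at high CO2, and the response differences of cpcG2 (-0.76) and cmpB (0.99). The fitted value of flv4 at high CO2 became 0.47, but flv4 was not well above background on these WT arrays, so this shows no rise.

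Averaging the arrays of a scan period, which leaves 3 values per WT group and 1 per mutant group and assumes that mutant values vary like WT, gave 804 genes for WT, 93 and 86 between strains at high and low CO2, 7 for the mutant response and 0 for the response difference (83 at an unadjusted p under 0.05 in limma). Of 284 named results 108 passed. With scan period also as a block, the numbers were 430, 283, 321 and 0 (253 unadjusted). Leaving out each array gave 1926 to 2034 genes for WT, 773 to 1500 and 537 to 1126 between strains at high and low CO2, 585 to 1098 for the mutant response and 14 to 139 for the response difference. It gave 50 to 55 list shifts, 237 to 282 named results, a correlation of responses of 0.837 to 0.853, and sll0822 at 0.22 to 0.39 at high and -0.48 to -0.41 at low CO2. The low counts came without a mutant array, which leaves 1 array assumed to vary like the others. Over the other alternatives 234 of 348 gene results and 35 of 120 list results changed call at least once. These counts leave out single arrays left out, the 2-fold threshold, the fits within a slide or scan period and the estimated correlation. The estimated correlation alone ended 52 list calls. Signal over background limits the dimmest genes, since only 77.7 to 94.1% of the spots of an array were well above it.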

Other observations

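The comparison of the strain differences between CO2 levels, the pairs of antisense transcripts and genes and the genes named in this part were chosen after their values were seen; the gene lists were not.

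The differences between the strains were largely shared between CO2 levels. Across genes, which are not independent replicates, the log2 fold changes of mutant against WT at high and at low CO2 correlated at r = 0.796 (Spearman's rho 0.752), with a slope of 0.74. Of these genes 484 were higher at both levels (144 for independent lists), 335 were lower at both (95.7) and 14 changed in opposite directions. All mutant arrays lie in one scan period and WT arrays of the same number share theirs, which the numbers for independent lists leave out. With WT replicates 5 and 6 alone, from the scan period of the mutant arrays, the correlation was 0.757. The nblA genes, which start phycobilisome breakdown, were higher at both, nblA1 (ssl0452) by 2.93 ± 0.35 and 2.57 ± 0.35 and nblA2 (ssl0453) by 2.58 ± 0.31 and 2.59 ± 0.31. sigB (sll0306), a group 2 sigma factor, was higher by 2.27 ± 0.17 (adjusted p = 2.74e-07) and 1.57 ± 0.17 (8.85e-06). sigI (sll0687) stood at -0.25 (0.242) at high CO2 and was higher by 1.37 ± 0.17 (3.22e-05) at low CO2, with a response difference of 1.63 ± 0.24 (0.00272). At high CO2 the sigma factors had a median of -0.25, a mean of 0.07 and camera's direction upwards (2 higher, 2 lower, 5 not passed, camera adjusted p = 0.998), and the type IV pili genes a median of 0.02 and a mean of 0.26 with camera's direction downwards (4 higher, 5 lower, 9 not passed, 0.957).

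Genes of glycogen and sugar breakdown moved in both directions in WT at low CO2. Of 15, 4 rose, 6 fell and 5 did not pass the test (11 adjusted over the list alone, median -0.35, camera adjusted p = 0.702). Of the glycogen phosphorylase genes, glgP1 (sll1356) rose by 1.33 ± 0.18 (adjusted p = 2.12e-05) and glgP2 (slr1367) fell by 1.41 ± 0.18 on the log2 scale (9.51e-06), and glgC (slr1176), which makes ADP-glucose for glycogen, fell by 1.58 ± 0.23. Of 8 photorespiration genes 1 rose, 4 fell and 3 did not pass (5 adjusted over the list alone, median -0.45, camera adjusted p = 0.563); glcD1 (sll0404), glycolate dehydrogenase, rose by 0.84 ± 0.16 and gcvH (slr0879) fell by 1.26 ± 0.13. Of 7 iron genes 5 fell and 2 did not pass (5 adjusted over the list alone, median -0.61, camera adjusted p = 0.231), with the iron transporter gene futA1 (slr1295) down by 1.93 ± 0.19 on the log2 scale. flv3 (sll0550) rose by 1.26 ± 0.28 and flv1 (sll1521) fell by 0.37 ± 0.11. The 5 hydrogenase genes had a median of 0.53 (2 rose, 3 not passed, camera adjusted p = 0.0982, adjusted p = 0.533 with an estimated correlation) and were called with the replicate block and with the slide series as a block. Medians were also small for the 4 high-light-inducible genes (-0.39, 4 not passed, camera adjusted p = 0.923), the 12 phosphate genes (0.25, 1 rose, 11 not passed, 0.231) and the 12 photosystem I genes (-0.30, 0.02 with quantile normalization, 1 rose, 1 fell, 10 not passed, 0.923). Within scan periods 1, 2 and 3 the photosystem I median was 0.35, -1.16 and -0.02, so its small value does not hold in each period.

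Of 100 genes of the plasmid pSYSA 32 rose in WT at low CO2, 5 fell and 63 did not pass the test (26 adjusted over the list alone, median 0.27, camera adjusted p = 0.00069, adjusted p = 0.317 with an estimated correlation). In the mutant-labelled arrays 14 rose, 2 fell and 84 did not pass (11 adjusted over the list alone, median 0.24, 0.23 with 2 genes at their bound, camera adjusted p = 0.0054, adjusted p = 0.512 with an estimated correlation). This call ended with normexp and quantile normalization together (median 0.07) and with the authors' series values (0.03). With the arrays of a scan period averaged, most of the single-gene calls in WT and all of those in the mutant-labelled arrays ended. The lists for the plasmids pSYSM, pSYSX and pSYSG held 0 genes among those tested. The phosphate transporter genes pstC2 (slr1248) and pstA2 (slr1249) were higher in the mutant-labelled arrays at high CO2 by 1.75 ± 0.34 (adjusted p = 0.00117) and 1.15 ± 0.21 (0.000713), and at low CO2 they stood at 0.37 and 0.40 (0.461 and 0.171). The phosphate list had a median of -0.34, a mean of 0.14 and camera's direction upwards at high CO2 (camera adjusted p = 0.541). Its median response difference was -0.71 (camera adjusted p = 0.0592, adjusted p = 0.871 with an estimated correlation), not called; it was called with the replicate block, the slide series as a block, the stricter filter, arrays of a scan period averaged and WT replicates 5 and 6 alone (-0.68).

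Of the features other than genes, 79 UTRs were higher and 248 lower in the mutant-labelled arrays at high CO2, 56 non-coding RNAs were higher and 172 lower, and 334 antisense transcripts were higher and 190 lower. Spacer11-2-x was not well above background on any mutant array there and was at least 33.6-fold lower against the WT arrays of all scan periods. Against only the WT arrays of the mutant arrays' scan period its fitted log2 difference was -4.40, which is smaller than that bound. The feature sll0485-as1 was at least 5.71-fold higher at high CO2 and at least 15.7-fold higher at low CO2. In WT, antisense transcripts and their genes were both changed at low CO2 in 491 of 1648 pairs, 328 of them in opposite directions (288 if the directions were independent) and 163 in the same, and across pairs the changes correlated at -0.209; in the mutant-labelled arrays 122 pairs were both changed, 94 in opposite directions (85.9 if independent). Ribosomal RNA features stood 0.34 to 0.41 higher at low CO2 in WT, and 0.66 to 0.87 in the mutant-labelled arrays, on the log2 scale. sll0823, whose tag is the next after sll0822, stood at -0.15 (adjusted p = 0.583) in mutant against WT at high CO2 and at -2.08 ± 0.20 (3.64e-06) at low CO2, with a response difference of -1.94 (0.00272); coordinates to place it were not available.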
